A study of Homo sapiens with 2 samples.

How the data were processed

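Gene expression was measured on 2 two-colour human oligonucleotide arrays, 1 of HEK293 cells expressing sLF and 1 of cells expressing ΔLF. Per the labels, the RNA of these cells carried Cy5 and the HEK293 RNA carried Cy3 on both arrays. Ratios are therefore Cy5 over Cy3, and a positive log2 ratio means a higher signal in the lactoferrin-expressing cells. The labels name HEK293 as the cells of both channels, but the extraction text in the labels names MCF-7, a breast cancer line, and the data used here do not settle this.

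Per the file headers, the deposited scanner files hold GenePix Pro intensity values of each spot and of its local background, with no normalization applied. The deposited percent columns give the share of a spot's pixels at the scanner's ceiling, per the file headers. The Cy3 channel was scanned at a gain of 390 on the sLF array and 420 on the ΔLF array, and the Cy5 channel at 520 on both. The deposited value table holds log2 ratios of the authors for 18367 of the 30968 human probes. How it was made is not given in the sources used here. Its columns had the sign of the scanner's Cy5 over Cy3 ratio and correlated with the ratios computed here at 0.944 (sLF) and 0.937 (ΔLF), across probes. Their medians were 0.037 and 0.0257, and the lowest value, −6.6439, equals a ratio of 0.01. Its filter and its exact normalization stay unknown, so it served as an alternative only.

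Intensities were background-corrected with normexp (offset 50) and normalized within each array by loess (span 0.3) in limma 3.58.1 under R 4.3.3. Control, empty and marked spots had weight 0 in the loess. Median spot intensities were used. The offset draws ratios of dim probes towards 0, so fold sizes there are understated. Spots marked by the scanning software were left out, which removed 4402 human probes on the sLF array and 5817 on the ΔLF array. A probe was well above background in a channel when its median foreground exceeded the local background by more than 2 background SDs. A probe entered a comparison when this held in both channels, or in all 4 for ΔLF over sLF. Counts are of probes at least 2-fold apart (a log2 ratio of at least 1 in size). Tables were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures with matplotlib 3.10.9. With 1 array per group no test was possible, and batch could not be separated from group.

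The steps were tested on simulated data, in 5 runs with the spot noise of the control probes and 200 changed probes. Of probes changed by a log2 size of 1.5, 66.7% were counted in the ΔLF simulation (17546 probes) and 68.7% in the sLF simulation (18139 probes). All of those changed by 3 were counted, with median estimates of 2.64 and 2.66. Between 8 and 13 unchanged probes per simulated ΔLF array and between 3 and 12 per simulated sLF array were also counted as at least 2-fold.

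Before the data were examined, a rule set which genes to name: lactoferrin, the 10 highest and 10 lowest genes of each comparison among those at least 2-fold, the leading members of fixed gene lists, every reported target of ΔLF, and genes at least 2-fold in opposite directions. Probe identifiers could not be matched to genes (0 of the identifiers were in the gene table, assembly GRCh38.p14). Lactoferrin, the 26 gene lists and the cell type markers were therefore not analysed. The 2 highest and 2 lowest probes of each comparison are named by identifier instead. Averaging over probes of a gene and print-tip loess were also not run, the latter because each slide had 1 print block.

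Alternatives planned before the data were examined changed the background correction, the normalization, the foreground summary, the filter on dim probes, the treatment of marked spots, the source of the values and the route between arrays. Removing a trend along the slide and leaving out probes at the scanner's ceiling were added after the data were seen. Some checks were also changed after a first value was known. Spot noise was first weighed by the simulated arrays alone (at most 13 false calls on a ΔLF array). The ratio of control-spot SDs was then used, because a simulation rests on its assumed noise. Bounds between the arrays' Cy5 channels were first computed over all probes measured in one Cy5 channel only. They were then also computed over probes with Cy3 signal on both arrays, because a bound of 91.47-fold raised the question of failed spots; both are given. The overlap of lists in simulated groups that share only a reference, with normal errors, was likewise added after the overlaps were seen. The gap between the 4 shared probes and other bright probes was computed with a limit that the choice of those probes meets by itself, so it supports nothing. A stray-fluorescence test on the 2 lowest sLF probes alone was tried, and its result went with stray fluorescence. It was dropped, since their values were already known, and the earlier test on all 20 lower probes was kept.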

Results

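The series asked how the secreted form of human lactoferrin (sLF) and its alternatively spliced form, which lacks the signal sequence (ΔLF), alter gene expression in HEK293 cells. Lactoferrin is an iron-binding glycoprotein of milk and other secretions. HEK293 is a human embryonic kidney cell line, and each form was expressed in it from an inducible, site-specifically integrated construct. The data were 2 two-colour oligonucleotide arrays, 1 per group. On each, RNA of the lactoferrin-expressing cells carried Cy5 and RNA of HEK293 cells carried Cy3. The labels do not say whether these HEK293 cells were parental, uninduced or vector controls, nor whether 1 preparation served both arrays. Where a shared reference is spoken of, it is assumed from the equal description. There were no replicate arrays and no dye swap, so no difference has a replicate check, no test was made and no p-value is given. The number of arrays limits the precision of every value. Each array was also scanned separately, so scan and group cannot be told apart.

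Each array held 30968 human probes, each spotted once. On the sLF array 17740 human probes (57.3%) were unmarked by the scanning software and well above background in Cy5, and 21746 (70.2%) in Cy3. On the ΔLF array these numbers were 16964 (54.8%) in Cy5 and 20876 (67.4%) in Cy3. Among them, the median intensity above local background was 274.5 in Cy5 and 118 in Cy3 on the sLF array, and 290 in Cy5 and 150 in Cy3 on the ΔLF array. Of the 7153 empty positions per array, at most 5 passed the same limit in any channel. Repeated control probes gave the error within an array. The pooled SD of the log2 ratio among spots of one control probe was 0.239 on the sLF array (57 control probes, 418 spots) and 0.249 on the ΔLF array (58 control probes, 426 spots). This is technical spread between spots and includes no variation between cultures.

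The files and the gene table used here do not pair the array's probe identifiers with genes. The level of lactoferrin itself, which would have checked the labels, and the 26 gene lists fixed beforehand were therefore not analysed here. Results are given by probe.

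Expression of sLF was set against the HEK293 reference first. Of 17270 probes well above background in both channels, 6 were at least 2-fold higher in the sLF cells and 20 were at least 2-fold lower, 0.15% in all. The SD of the log2 ratio over these probes was 0.225, against a pooled spot SD of 0.239 and a median spot SD of 0.121 per control probe. Higher probes made up 23.1% of those past the limit. On simulated sLF arrays, between 3 and 12 unchanged probes were counted as at least 2-fold. Of the 6 higher probes measured here, 4 were at the scanner's Cy5 ceiling, and 2 remained without them. With local background subtracted, 37 were higher and 100 lower. Over all probes listed in the authors' deposited table, 90 were higher and 189 lower. With median centring in place of the intensity-dependent correction, 176 probes were higher and 12 lower, so that 93.6% were higher; neither the number of higher probes nor the direction of the split on this array was stable to that choice. PH_hs_0025190 had a log2 ratio of 1.25 (2.38-fold higher) and PH_hs_0039308 one of 1.13. The Cy5 signal of PH_hs_0039308 was at the scanner's ceiling, so its ratio is understated and the order of these probes is not settled. With median centring they were at 1.87 and 1.93. The lowest were PH_hs_0023394, at −4.97 (31.43-fold lower), and PH_hs_0038203, at −3.32 (9.99-fold lower), or −5.00 with local background subtracted. Neither of these lowest probes had a usable value on the ΔLF array. The spot of PH_hs_0023394 was marked by the scanning software there, and PH_hs_0038203 was not well above background in both channels. Their Cy3 intensities were 16703 and 763 on the sLF array. On the ΔLF array, with Cy3 RNA of the same description, they were 52 and 66, over local backgrounds of 46 and 51. Lower expression with sLF therefore cannot be told apart from a Cy3 signal present on 1 array only.

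Expression of ΔLF was set against the same kind of reference on the other array. Of 16538 probes, 222 were at least 2-fold higher in the ΔLF cells and 56 were at least 2-fold lower, 1.68% in all. Higher probes made up 79.9% of these, and 86.5% with median centring, which gave 301 higher and 47 lower. Over the probes compared here, the authors' deposited table gave 514 higher and 134 lower, so that 79.3% were higher. Over all probes it lists, without the filter on dim probes used here, 687 were higher and 685 lower, so that 50.1% were higher. The number past the limit was 10.7 times that of the sLF array, and 1.9 times with median centring. The SD of the log2 ratio was 0.332, against a pooled spot SD of 0.249 and a median of 0.108. On simulated ΔLF arrays, between 8 and 13 unchanged probes were counted as at least 2-fold. At a limit of 1.5-fold, 802 probes were higher and 389 lower, against 71 and 213 on the sLF array. The highest ratios were those of PH_hs_0002591, at 2.97 (7.83-fold higher), and PH_hs_0024850, at 2.80 (6.98-fold higher). With mean in place of median spot intensities they were 2.25 and 2.77, so their order also depended on that choice. PH_hs_0002591 was also higher on the sLF array, at 1.03, where its Cy5 signal was at the ceiling. PH_hs_0024850 had a ratio of −0.28 there. The lowest were PH_hs_0035428, at −3.61 (12.23-fold lower), and PH_hs_0029175, at −2.55 (5.86-fold lower), or −4.25 with mean spot intensities. The spot of PH_hs_0035428 was marked by the scanning software on the sLF array, so it has no value there. Its Cy3 intensity was 6350 on the ΔLF array and 75 on the sLF array, equal to the local background there. Lower expression with ΔLF cannot be told apart from a Cy3 signal present on 1 array only. PH_hs_0029175 was lower on both arrays, with −2.74 (6.68-fold lower) in the sLF cells. A difference between the numbers of probes on the arrays was not tested.

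**Figure D1:**
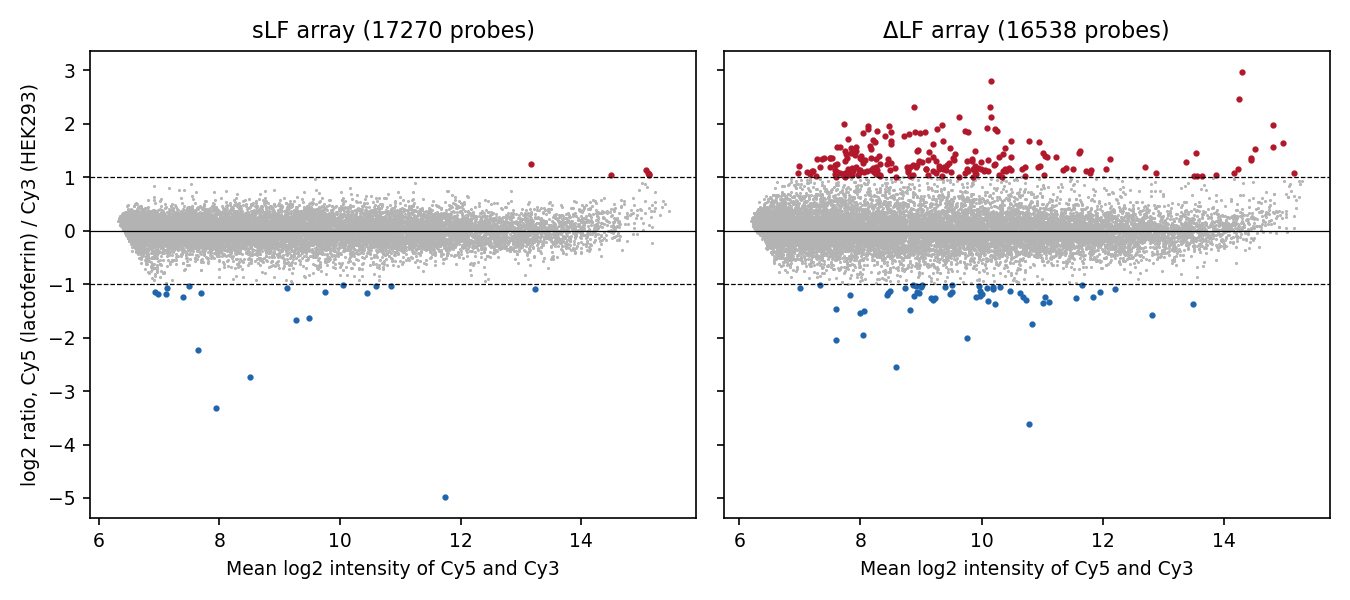
The log2 ratio of lactoferrin-expressing cells (Cy5) over HEK293 reference (Cy3) is plotted against the mean log2 intensity of each probe, for the sLF array on the left (17270 probes) and the ΔLF array on the right (16538 probes). Red points are at least 2-fold higher (6 and 222), blue points at least 2-fold lower (20 and 56), and dashed lines mark 2-fold.

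The direct question of the design, how the forms differ from each other, was addressed by the difference between the arrays' log2 ratios. In 14945 probes well above background in all 4 channels, 248 were at least 2-fold higher with ΔLF than with sLF and 38 were at least 2-fold lower. The 2-fold limit was 2.9 times the spot SD of this difference, 0.345. The SD of the difference over the probes was 0.344, no larger than that. That spot SD comes from the pooled SDs, which include single control probes with SDs up to 1.196 (sLF) and 1.009 (ΔLF). The median SD per control probe was smaller, 0.121 (sLF) and 0.108 (ΔLF). The match of 0.344 and 0.345 therefore does not show that the spread is spot noise. False calls were not simulated for this comparison, so how many probes spot noise alone would put past the limit is not known. Higher probes made up 86.7%, and 55.8% with median centring, which gave 198 higher and 157 lower. Of the 248 higher probes, 184 were among those 198. The highest differences were 3.08 for PH_hs_0024850 (8.48-fold), or 3.87 from the Cy5 channels alone, and 3.04 for PH_hs_0023485 (8.2-fold), the latter from −0.91 on the sLF array to 2.12 on the ΔLF array. The lowest were −1.79 for PH_hs_0025190 (3.46-fold) and −1.53 for PH_hs_0024091 (2.89-fold), whose ratios were −0.48 with sLF and −2.01 with ΔLF. Of the 248 probes, 160 were also at least 2-fold higher than the reference on the ΔLF array. Their median log2 ratio to the reference was 1.13 on the ΔLF array and −0.28 on the sLF array. Because probes were chosen for a difference of at least 1, the gap between these medians follows in part from that choice. It does not show that sLF lowered them. Over these 248 probes the median change of the Cy5 channel between arrays was 1.79, and that of the Cy3 channel was 0.04.

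Across the 14945 probes, which are not independent replicates, the log2 ratios of the arrays had a Pearson correlation of 0.282 and a Spearman correlation of 0.336. Groups sharing only 1 reference were simulated 200 times, with independent deviations of equal spread for each RNA. Their spot noise was taken from the median SD per control probe, and they gave a Pearson correlation of 0.418. That value follows from these settings. The larger pooled spot SD would lower it and was not simulated, so no conclusion is drawn from the gap. The observed covariance was 0.0208 and the simulated one 0.0335. A reference shared between the arrays, and the shared dye orientation, would add to the observed correlation, and with 1 array per group their part could not be separated. In these probes 4 were at least 2-fold higher on both arrays. Independent lists of the same lengths would share 0.069 probes. Lists of those lengths from the simulated groups shared 1.09 on average, with 4 or more in 1 of the 200. All 4 were at the scanner's ceiling in Cy5 on the sLF array and 1 of them also on the ΔLF array, so these ratios are understated. Their log2 ratios ranged from 1.03 to 1.13 on that array and from 1.57 to 2.97 on the ΔLF array. With a trend along the slide removed, 1 probe was higher on both, and without ceiling probes 0 were. With median centring 48 were, with local background subtracted 10, and with a normexp offset of 10 there were 8. The size of this overlap therefore depended on the processing. There were 3 probes lower on both arrays, against 0.0319 for independent lists. In the simulation it was 0.74 on average, with 3 or more in 4 of the 200. The simulation left out the scanner's ceiling and any trend along the slide, so its counts set no chance level for either overlap. One probe chosen after its values were seen, PH_hs_0027748, went opposite ways, at −1.14 with sLF and 1.37 with ΔLF.

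**Figure D2:**
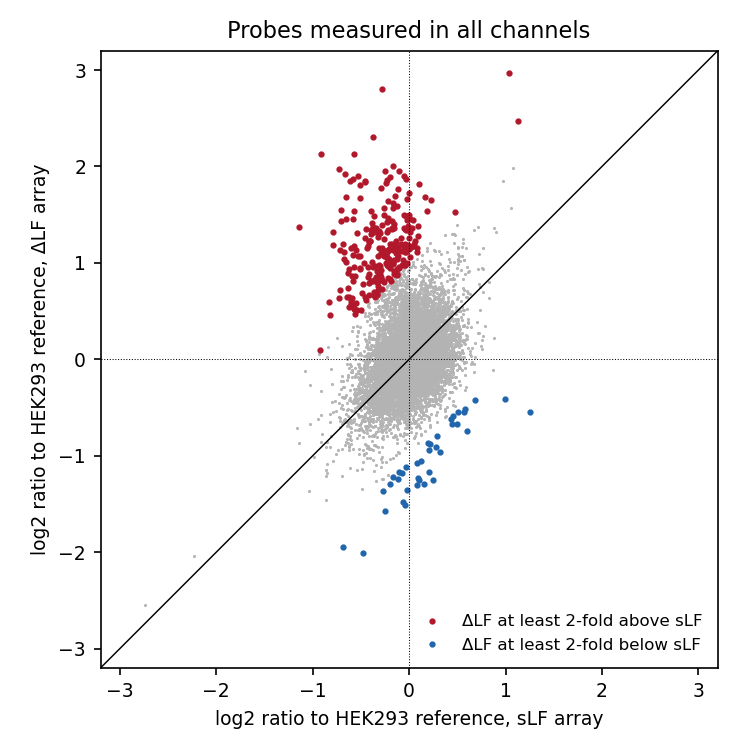
The log2 ratio to the HEK293 reference on the ΔLF array is plotted against that on the sLF array for the 14945 probes measured in all 4 channels. Red points (248) were at least 2-fold higher with ΔLF than with sLF, blue points (38) at least 2-fold lower, and the solid line marks equal ratios.

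Control probes, which took no part in these comparisons, were measured repeatedly on both arrays. What they measure is not known here. Of the 55 measured on both arrays, 12 on the sLF array and 13 on the ΔLF array were themselves at least 2-fold apart in Cy5 over Cy3. Of 55 such probes, 23 differed between the arrays by more than 2 SE of their spots, 20 of them higher on the ΔLF array and 3 lower, with a median difference of 0.09 over all 55. At least 2-fold, 1 differed. This was PH_c_0000051, singled out after its values were seen, with a log2 ratio of −0.51 ± 0.305 (SD, 6 spots) on the sLF array and 1.03 ± 0.103 (SD, 6 spots) on the ΔLF array. PH_c_0000025, spotted 102 times, had log2 ratios of 0.05 ± 0.113 and 0.114 ± 0.091 (SD over spots).

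**Figure D3:**
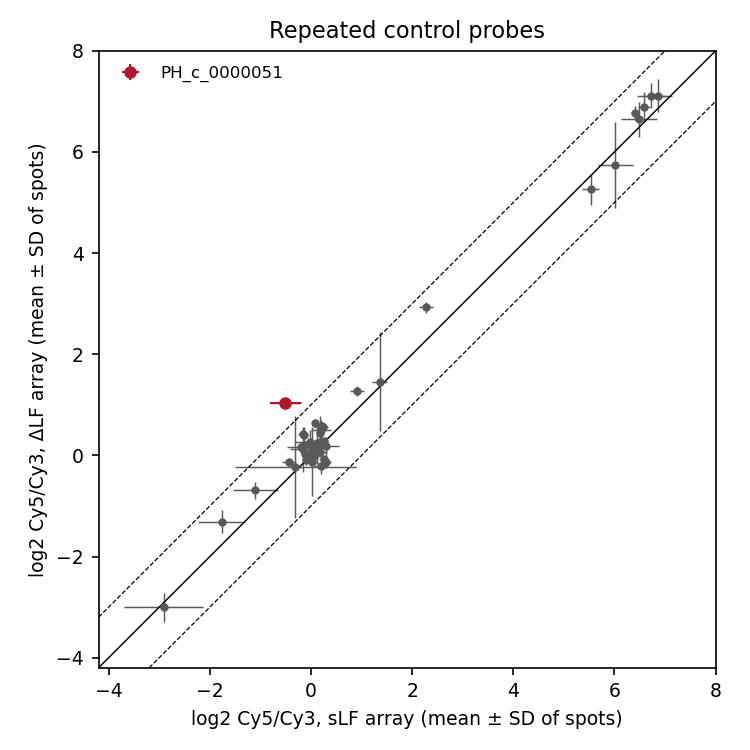
The mean log2 ratio of Cy5 over Cy3 on the ΔLF array is plotted against that on the sLF array for the 55 control probes with repeated spots, with bars for the SD among spots. The solid line marks equal ratios, dashed lines mark a 2-fold difference, and PH_c_0000051, in red, lies beyond it.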

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

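The tests of a lower reference signal, spot noise, slide or scan, and stray fluorescence in this part were chosen only after the result was seen; those of a dye effect were written before their value was computed, but after the 4 probes were known.

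PH_hs_0027748 stood out because its ratio went opposite ways on the arrays, −1.14 with sLF and 1.37 with ΔLF, a difference of 2.51 that was not tested. PH_c_0000051 stood out as a signal in control spots used in no comparison, with a difference of 1.54 between the arrays.

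More probes were at least 2-fold apart from the reference on the ΔLF array (278) than on the sLF array (26), 10.7 times as many, and 1.9 times as many with median centring (348 and 188). For the 248 probes higher with ΔLF than with sLF, the Cy3 channel argued against a lower reference signal on the ΔLF array. Its median change was 0.04 (quartiles −0.17 and 0.27), while Cy5 changed by 1.79. Over all 14945 compared probes Cy5 also varied more than Cy3 between the arrays (SD 0.57 and 0.33). The 248 held 160 of the 206 probes higher than the reference on the ΔLF array and measured on both. The other higher probes and the 56 lower ones were not covered, so this does not decide for all 278. More spot noise was not seen in the control spots, whose pooled SD was 1.04 times as large on the ΔLF array, against 1.48 for the human probes. The median SD per control probe was 0.108 there and 0.121 on the sLF array. The 95% interval of the ratio, 0.94 to 1.15, assumed normal errors. Single control probes had SDs up to 1.009 (ΔLF) and 1.196 (sLF), so it may be too narrow. Human probes were spotted once, so their own spot noise was not measured and this does not decide for them. Of 55 control probes, whose targets are not known here, 20 were higher and 3 lower on the ΔLF array by more than 2 SE. A difference between slides, scans or labelling reactions cannot be told apart from the group, because there was 1 array per group. An effect of ΔLF itself stays open beside it, untested.

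Of the 20 probes at least 2-fold lower on the sLF array, 6 (30.0%) had a Cy3 signal at least 4-fold brighter there than on the ΔLF array, against 0.88% of all compared probes. On the ΔLF array the matching numbers were 5 of 56 lower probes (8.93%) and 0.39%. Stray Cy3 fluorescence on single spots may therefore account for some of them, but the other 14 did not reach that limit and no value decides for the set. Spots that failed on the ΔLF array would give the same picture; 9 of the 20 (45.0%) were not well above background in Cy3 there, against 6.3% of all. No biological explanation was tested.

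The 4 probes higher on both arrays were among the brightest, where ratios stayed above 0 after loess. The 100 brightest other probes had a median log2 ratio of 0.31 (SD 0.33) on the ΔLF array and 0.23 (SD 0.25) on the sLF array, below the 4 probes' 1.57 to 2.97 and 1.03 to 1.13, which the scanner's ceiling understates for 1 and 4 of them. Because the 4 were chosen for ratios of at least 1 on both arrays, this gap decides nothing, and a dye effect on bright spots stays open. On the ΔLF array 3 of the 100 were at least 2-fold higher, the highest at 1.64, and on the sLF array 0 were, the highest at 0.90. With a slide trend removed, 1 probe was higher on both, and without ceiling probes 0 were. With median centring, which makes no intensity-dependent correction, 48 were. A response to both forms also stays open, untested. Of 200 simulations of groups sharing only a reference, 1 shared as many probes. The simulation had normal errors and left out the scanner's ceiling, the ratios above 0 of bright spots and the slide trend. It therefore sets no chance level for these 4 probes.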

How the results depend on the processing

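Removing a slide trend and leaving out ceiling probes were chosen after seeing the data. No named probe's value changed sign under the alternatives run, but median centring turned the sLF array's split from 23.1% to 93.6% higher. Of 110 recomputed counts and correlations, 70 stayed, counts within 1.5 times and correlations within a 95% interval over probes. Counts were judged by size, not by the probes they held. With mean spot intensities 28 were lower on the sLF array, with 13 of the main 20 among them. On the ΔLF array 214 of 222 higher and 51 of 56 lower stayed. The authors' deposited table kept 3 of 6 higher and 12 of 20 lower sLF probes, and did not list 1 and 8. Of 105 values of named probes, 87 stayed within 1 spot SD. In the 12 alternatives that gave both counts and could change them, the ΔLF array had 1.9 to 18.3 times as many probes at least 2-fold as the sLF array. The 1.9 came from median centring and the 18.3 from scaling the arrays to one spread. Counts below run higher then lower, and the cause of a change was not tested unless stated. With a normexp offset of 10, the sLF array gave 13 and 52, the ΔLF array 340 and 106, ΔLF over sLF 68 lower, and 8 and 6 probes were shared. With local background subtracted, these were 37 and 100, 491 and 197, 452 and 123, with 10 and 8 shared. A smaller or no offset shrinks dim ratios less by construction. With median centring, the sLF array gave 176 higher, ΔLF over sLF 157 lower, the correlation was 0.306 and 48 were higher on both. With no filter on dim probes, 36 were lower on the sLF array, 6 lower on both, and the correlation was 0.328. With a limit of 4 background SDs, 12 were lower on the sLF array. The authors' deposited table, over probes compared here, gave 27 and 58, 514 and 134, and 401 and 93, with 10 and 7 shared. Over all its listed probes the authors' deposited table gave 90 and 189, 687 and 685 (50.1% higher), and 728 and 447. Scaling the arrays to one spread over all spots, empty and dim ones included, gave 3 higher on the sLF array and 2 on both. Higher and lower together were 19 on the sLF array and 348 on the ΔLF array. It shrank the sLF ratios and stretched the ΔLF ratios, so it did not equalise the spread of the compared probes (SD 0.225 and 0.332 before). Removing a slide trend gave 3 higher on the sLF array, of which 2 were among the 6, and 1 on both, with a correlation of 0.231. Without ceiling probes, 2 were higher on the sLF array and 0 on both. All 4 shared probes were at the Cy5 ceiling on the sLF array, so this choice removed them. The Cy5 channels alone gave 115 lower with ΔLF than sLF. Restricting to the upper intensity range removed no counted probe, says nothing about stability and is not among the 110. Print-tip loess, the mean over a gene's probes, and the alternatives for lactoferrin and the gene lists were not run, for want of print blocks and gene names. No paired analysis was possible because each group had 1 array. Signal over background and marked spots limit the comparisons to 55.8%, 53.4% and 48.3% of human probes.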

Other observations

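The bounds that require Cy3 signal on both arrays were added only after the first bounds were seen. Between the Cy5 channels, 1394 probes were well above background on the ΔLF array only, of which 46 were at least 2-fold higher there by their bound. With Cy3 signal required on both arrays, these were 592 and 19, and the largest bound was still 64.99-fold, against 91.47-fold without that requirement. In the other direction 2046 probes were measured in Cy5 on the sLF array only, 10 of them at least 2-fold, and 1217 and 3 with Cy3 required, with a largest bound of 9.87-fold in both sets. Within the sLF array, 470 probes were measured in Cy5 only and 4476 in Cy3 only, of which 0 were at least 2-fold higher and 13 at least 2-fold lower by their bound. Within the ΔLF array these were 426 and 4338 probes, with 4 higher and 5 lower. In each bound, the channel not well above background took its own value, or a floor where the floor was higher. The floor was the lowest value counted as well above background in that channel of that array. A spot's own background limit was not used, so the bounds are not guaranteed minimum folds. Bounds within an array compare dyes without a dye swap, and those between arrays compare separately scanned slides.

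The deposited value table did not list 12601 human probes. Of the probes measured in both channels here, 2456 on the sLF array and 1849 on the ΔLF array were not listed, among them 1 and 14 at least 2-fold higher and 8 and 12 at least 2-fold lower.

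With the slide's rows cut into 10 equal bands, the median log2 ratio was 0.12 over the top band and −0.07 over the bottom band on the sLF array, and 0.14 and −0.08 on the ΔLF array.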
